A study of Mus musculus with 24 samples.

How the data were processed

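Chromatin accessibility was measured by ATAC-seq in bone marrow-derived macrophages, grown for 7 days from the marrow of male mice at postnatal day 28, per the labels' protocols. The 24 libraries came from 8 biological replicates, taken here as 8 animals with 3 libraries each. Animals 1, 4, 6 and 7 were C57BL6/J and animals 2, 3, 5 and 8 were BTBR. Cultures received media alone, lipopolysaccharide (LPS) at 100 ng/ml for 24 hours (LPSx1), or LPS at 100 ng/ml for 4 hours, a wash, about 20 hours in plain medium and LPS again for 24 hours (LPSx2). Each reaction held 50000 cells, and 50 bp paired-end reads were generated, per the labels' protocols. Lane 1 held animals 1 and 2, lane 2 animals 3 and 4, lane 3 animals 5 and 6, and lane 4 animals 7 and 8, so each lane held 1 animal of each strain and all 3 treatments. The additional PCR cycles ranged from 6 to 8 in lanes 1 and 2 and from 5 to 13 in lanes 3 and 4, per the labels.

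Alignment used the mm10 build of the mouse genome, fragments were limited to nucleosome-free ones under 147 bp, and peaks were called with HOMER in each library separately, per the submitters' processing notes. Those notes also name Trimmomatic 0.38, SAMtools 1.8, Picard 2.18.4 and bedtools, and they do not name the aligner or give a version for HOMER or bedtools. The names of the lists state a false discovery rate of 0.01 and the removal of blacklisted regions. Each deposited list gives the position of every peak, 201 bp wide, with a peak score that the authors deposited without stating its scale. The score ran in steps of 0.5 and was used only to rank peaks within a list. The number of reads per library is not given, so depth is known only through the number of peaks, which ranged from 299 to 127291 per list. No peak passed the end of a chromosome in the GRCm38.p6 reference, the assembly of mm10, and all coordinates below are 1-based in mm10.

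Of the 24 lists, 7 held most peaks in duplicate at the same or overlapping positions with different scores, with 66.7% to 87.4% of peaks overlapping another. They were all 3 lists of C57BL6/J animal 1 and the media and LPSx2 lists of BTBR animal 3 and C57BL6/J animal 4. In the other 17 lists at most 0.213% of peaks overlapped another. Overlapping peaks were merged to the higher-scoring one in every list, a choice made after the lists were seen. The C57BL6/J animal 6 lists for media (299 peaks) and LPSx2 (1879 peaks) were left out because they held fewer than 5000 peaks, which left 7 media, 8 LPSx1 and 7 LPSx2 libraries.

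Within a lane, every list was limited to its highest-scoring peaks so that all had the length of the shortest kept list, which was 11349, 22037, 16045 and 13957 peaks in lanes 1 to 4. Each peak was assigned to the nearest transcription start site (TSS) of 21951 protein-coding genes within 100 kb. The 9123 genes with a mean of at least 0.5 peaks were tested. Because the lists of a lane have equal length, a higher peak number at a gene means a larger part of the strongest peaks, not a rise in total accessibility. Peak numbers were fitted in R 4.3.3 with limma 3.58.1 (trend and robust), using 6 groups of strain by treatment and the lane as a covariate, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Treatment contrasts averaged the strains with equal weight, interaction terms tested whether the response differed between strains, and the strain contrast used duplicateCorrelation (statmod 1.5.0) with the animal as random effect. The consensus correlation was -0.00469, so this fit treated the libraries of an animal as nearly independent.

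Regions were the union of the length-limited lists, merged where they overlapped by at least 1 bp, which gave 44996 regions. A region counted as gained or lost between treatments when it was detected in one and not the other in at least 5 of 7 animals and the reverse held in none. It counted as strain-specific when all 4 animals of one strain and none of the other held it in most of their libraries. The number of such regions was tested by exact permutation, swapping treatments within animals (64 arrangements) or animals between strains (35 splits). For 18 gene lists, the percent of gene-assigned peaks lying at members was compared. For 11 motifs, the percent of distal peaks (over 1 kb from any TSS) with the consensus sequence in the 201 bp window was compared. Both used 2-sided exact permutation of treatments among libraries within lanes, or of animals between strains, with Benjamini-Hochberg adjustment within a comparison. Regions and shares were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and tables in R were handled with the data.table package (version 1.17.8). The percent of peaks within 1 kb of a TSS was added after the lists were examined.

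The consensus sequences were GGGRNWYYCC for NF-kB, TGASTCA for AP-1, GAAANNGAAA for the interferon-stimulated response element (ISRE), GAGGAAGT for PU.1, TTGCNNAA for C/EBP, TTCCNGGAA for STAT, TGACGTCA for CRE, TCACGTGA for the E-box of the MiT family, CCASYAGRGGGC for CTCF, GCGCATGCGC for NRF1 and GGGGCGGGG for SP/KLF. The gene lists were inflammatory cytokines and mediators, NF-kB pathway and feedback regulators, interferon-stimulated genes, antimicrobial, acute-phase and scavenger genes, the LPS sensing pathway, the AP-1 family, macrophage identity, alternative activation, cholesterol efflux and LXR targets, cell cycle, antigen presentation, housekeeping, and markers of B cells, T and NK cells, neutrophils and granulocyte precursors, dendritic cells, stromal cells and fibroblasts, and erythroid, megakaryocyte and mast cells. The comparisons, the gene lists, the motifs, the minimum of 5000 peaks and the rule for named genes were fixed before the data were examined. That rule takes the 12 genes with the largest rise and the 10 with the largest fall among those that passed, up to 4 members of each list with the largest change whether or not they passed, and 3 regions per direction. Where no gene passed, it takes the 5 with the smallest p in each direction. Further list members that passed, and genes nearest to several changed regions, were named after the values were seen. Of the genes this rule names, 1 is not reported here.

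The replicate numbers pair the libraries, since the labels give the 3 libraries of a strain that share a biological replicate number 1 library per treatment. Deviations from the group means correlated across genes in each of the 21 pairs of libraries with a shared number (0.194 to 0.798, median 0.507), against a median of -0.240 over 60 other pairs. The deviations were not adjusted for lane. Libraries with a shared number also shared a lane and its list length, and the other pairs did not, so these correlations cannot tell animal from lane. The fit with the animal as a block was run as an alternative. The limma step was tested on simulated data for LPSx1 against media with 200 altered genes among 9123. With noise drawn from the measured spread, 12%, 77% and 94% of genes were recovered after adding 1, 2 or 3 peaks, with 1, 8 and 13 other calls. With Poisson noise, 0%, 3% and 52.5% were recovered, with 0, 0 and 3 other calls. In the region step, 200 of 200 altered regions were recovered, with 142 other calls.

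Alternatives were lists as deposited, lists limited to the shortest of all lanes or to the shortest of each animal, the stronger 50% of each list, no library left out, no lane covariate, peaks within 25 kb of a TSS, log2 peak number with 0.5 added, no filter on low peak numbers, LPSx1 libraries alone for the strains, all peaks in place of distal peaks for motifs, an overlap of at least 50% of a peak for regions, and each animal left out in turn. Those added after the data were seen were unmerged peaks, the 7 lists with duplicates left out, lanes 1 and 2 or lanes 3 and 4 alone, distal peaks alone for genes, peak numbers divided by list length for libraries that stood apart from their group, the animal block with lists limited within an animal, and 1 value per animal for the strains. For the number of peaks per list, merged lists, the animal block and the exclusion of lists under 5000 peaks were also added then.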

Results

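Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in bone marrow-derived macrophages from 4 C57BL6/J and 4 BTBR T+ Itpr3tf/J (BTBR) male mice. BTBR is an inbred strain studied for autism-like behaviour and altered immune responses. Cells of each animal were kept in media, given a single dose of LPS (LPSx1) or given a second dose after a first, short one (LPSx2). LPS is a component of the outer membrane of Gram-negative bacteria that macrophages sense through Tlr4. The design asks how a single and a repeated exposure to LPS change chromatin, whether a repeated exposure leaves a different state, and whether the strains differ.

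The deposited lists held 19621 ± 15850 peaks (SD, n = 4; 299 to 38751) in C57BL6/J media, 36082 ± 12500 (25342 to 54046) in C57BL6/J LPSx1 and 36578 ± 24186 (1879 to 58126) in C57BL6/J LPSx2. In BTBR they held 42598 ± 25306 (SD, n = 4; 16047 to 65300) in media, 48513 ± 45628 (13959 to 112455) in LPSx1 and 54289 ± 52309 (15628 to 127291) in LPSx2. On the log2 scale the number of peaks per list differed by 1.00 between LPSx1 and media (exact permutation p = 0.267, higher in 5 of 8 animals) and by 0.71 between LPSx2 and media (exact permutation p = 0.392, higher in 6 of 8). Without animal 6, whose media list held 299 peaks, these became 0.233 and 0.437, and without the 2 lists under 5000 peaks 0.169 and 0.437. LPSx2 against LPSx1 gave -0.29 (exact permutation p = 0.698), which became 0.20 without animal 6 and 0.27 without those 2 lists. BTBR against C57BL6/J gave 0.98 (exact permutation p = 0.514, n = 4 animals each), which became 0.01 without animal 6. All these values are for lists as deposited. Duplicates lay in the media and LPSx2 lists of animals 1, 3 and 4, but with LPSx1 only in animal 1. In animal 3, for example, the lists held 65300 peaks in media, 50116 with LPSx1 and 57055 with LPSx2. After merging they held 36182, 50091 and 33339. The differences between treatments above thus depend in part on the duplicates. List length as deposited did not pass a test between any groups, but it varied too widely to rule out a difference.

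A single exposure to LPS was followed by more of the strongest peaks at Pde4b, Ltbp1 and Slc31a2 and fewer at Hes1, Cd300a and Mthfs. Pde4b, a phosphodiesterase that degrades cyclic AMP (chromosome 4, 102087543 to 102607259, mm10), rose by 5.53 ± 0.647 peaks (difference ± SE, limma adjusted p = 0.000722). It went from 5.43 ± 2.07 in media (SD, n = 7) to 10.5 ± 4.11 (SD, n = 8) and was higher in 7 of 7 animals. Ltbp1, which stores latent TGF-beta in the matrix, rose from 1.43 ± 0.535 to 5.25 ± 1.58 peaks (adjusted p = 0.00187, 7 of 7 animals). The copper transporter gene Slc31a2 rose from 3.00 ± 2.24 to 7.38 ± 3.96 (adjusted p = 0.00663, 6 of 7). The glutaredoxin Glrx (6.71 ± 2.63 to 9.63 ± 3.16, 6 of 7 animals), the cystine transporter Slc7a11 (1.86 ± 1.46 to 4.88 ± 1.96, 7 of 7) and Rassf6 (0.714 ± 1.11 to 3.63 ± 2.13, 6 of 7) also rose. Hes1, a transcriptional repressor induced by Notch (chromosome 16, 30064384 to 30067796), fell by 3.17 ± 0.468 peaks (adjusted p = 0.00294). It went from 4.57 ± 1.72 to 1.63 ± 0.518 and was lower in 7 of 7 animals. The inhibitory myeloid receptor gene Cd300a fell from 4.57 ± 1.51 to 1.38 ± 1.30 (adjusted p = 0.00128, 7 of 7). Mthfs of folate metabolism fell from 5.43 ± 2.23 to 1.88 ± 1.13 (adjusted p = 0.00523, 6 of 7) and the kinase gene Sgk1 from 5.29 ± 2.36 to 2.38 ± 1.85 (adjusted p = 0.00447, 7 of 7).

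In all, 301 genes rose and 209 fell among 9123 tested, with 1980 at an unadjusted p under 0.05 where 456 would be expected by chance. Fewer genes passed with no lane covariate and in the stronger 50% of each list. The balance of rises and falls varied with the choices, with 614 and 141 for distal peaks alone, 174 and 179 for peaks within 25 kb of a TSS, 358 and 471 with no filter on low peak numbers and 325 and 339 with unmerged peaks. The other named rises were Tnfrsf1b, a receptor for TNF, Ppm1h, the DNA demethylase gene Tet2, Cd47, Ncoa7 and Atp6v1g3, with differences of 3.25 to 4.16 peaks. The other named falls were Zfp36l2, Elmo1, Maml3, Tex44, Itgb5 and Arid1a, with differences of -3.97 to -2.50. Of these 22 named genes, 10 passed with each animal left out in turn, the 9 with values above other than Slc7a11 plus Tex44. The other 12 lost their call without at least 1 animal, with adjusted p up to 0.143. Tnfrsf1b lost it without animal 1 (adjusted p = 0.0515), Cd47 without animal 4 (0.0628) and Slc7a11 without animal 7 (0.0512). Ppm1h, Tet2, Ncoa7, Atp6v1g3, Zfp36l2, Elmo1, Maml3, Itgb5 and Arid1a each lost it without any single one of 4 to 7 animals. The count fell to 295, 232, 202, 200, 191 and 265 genes without animals 1, 3, 4, 5, 7 and 8, and no other of 64 arrangements of treatments within animals gave more than 179. It was 112 in lanes 1 and 2 alone (51 of them among the 510). No count is given for lanes 3 and 4 alone, where C57BL6/J media and LPSx2 had 1 library each. The count was 0 with lists limited within an animal (382 with the animal as a block). It was also 0 with lists as deposited, where Zfp36l2, Mthfs, Elmo1, Maml3 and Sgk1 lay on the other side of 0. In the stronger 50% of each list Hes1 lay on the other side of 0.

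Among the lists fixed in advance, peaks at interferon-stimulated genes rose from 0.155% ± 0.0289 of gene-assigned peaks in media (SD, n = 7) to 0.281% ± 0.0687 with LPSx1 (SD, n = 8; exact permutation adjusted p = 0.0278, higher in 7 of 7 animals), by 0.159 percentage points in lanes 1 and 2 and 0.101 in lanes 3 and 4. This call was lost with lists as deposited (0.0989 points, adjusted p = 0.0556), and 0 of the 18 list shares passed with those lists, in the stronger 50% of each list or without the 7 lists with duplicates. Of 26 members tested, 4 rose (Cxcl10, Gbp5, Parp14 and Rsad2), 0 fell and 22 did not pass, and 9 rose when adjusted over the list alone. Rsad2, which encodes the antiviral protein viperin, rose from 0.429 ± 0.535 to 2.63 ± 1.19 peaks (limma adjusted p = 0.0188) and Parp14 from 0.143 ± 0.378 to 1.63 ± 1.06 (adjusted p = 0.00447), both in 7 of 7 animals. Peaks at inflammatory cytokines and mediators rose from 0.164% ± 0.0346 to 0.273% ± 0.116 (exact permutation adjusted p = 0.0389, 6 of 7 animals), a call lost with treatments swapped within animals (adjusted p = 0.0804), and by 0.178 points in lanes 1 and 2 but 0.0458 in lanes 3 and 4. Of its 22 members tested, Il12b and Ptges, the synthase of prostaglandin E2, rose, and 6 rose when adjusted over the list alone. Il1b, with a difference of 2.75 ± 1.64 peaks, did not pass (limma adjusted p = 0.358). Peaks at antimicrobial, acute-phase and scavenger genes stood at 0.189% ± 0.0392 and 0.281% ± 0.109 (exact permutation adjusted p = 0.0556, 7 of 7). In animal 8 this share hardly changed (0.145% to 0.151%). Of 20 members 3 rose (Camp, the formyl peptide receptor gene Fpr1 and Slc7a11), and 5 did when adjusted over the list alone.

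Peaks at housekeeping genes fell from 0.221% ± 0.0289 to 0.185% ± 0.0210 (exact permutation adjusted p = 0.0278, lower in 7 of 7 animals). Of 14 members of the AP-1 family tested, Jund fell from 2.29 ± 0.951 to 0.750 ± 1.04 peaks (limma adjusted p = 0.0101, 6 of 7 animals), and 1 rose and 6 fell when adjusted over the list alone. The share of that list stood at 0.272% ± 0.0562 and 0.219% ± 0.0583 (exact permutation adjusted p = 0.256). It changed by -0.105 points in C57BL6/J (n = 3) and -0.000517 in BTBR (n = 4). This strain difference did not pass (exact permutation adjusted p = 0.706). Of 23 NF-kB pathway and feedback regulators tested, Bcl3 rose and Sqstm1 fell, with 2 up and 2 down when adjusted over the list alone (list share 0.456% ± 0.0551 and 0.494% ± 0.0797, exact permutation adjusted p = 0.616). Of 23 macrophage identity genes tested, Lyz2 rose and Lgals3 fell, with 4 up and 4 down when adjusted over the list alone (exact permutation adjusted p = 0.949 for the share). In the LPS sensing pathway 0 of 19 members passed with limma, 0 did when adjusted over the list alone and Tlr4 had the largest difference (2.52 ± 0.842 peaks, adjusted p = 0.0951). The share of that list stood at 0.256% ± 0.0443 and 0.291% ± 0.0367 (exact permutation adjusted p = 0.0635).

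Of the remaining lists, Fasn fell among 18 cholesterol efflux and LXR target genes (1 adjusted over the list alone). By limma 0 of 13 alternative activation genes (3 adjusted over the list alone), 0 of 20 cell cycle genes and 0 of 12 antigen presentation genes (0 each adjusted over the list alone) passed. The shares of these 4 lists had exact permutation adjusted p of 0.616, 0.951, 0.951 and 0.951. Among markers of other cell types, peaks at stromal and fibroblast markers rose from 0.0217% ± 0.00410 to 0.0376% ± 0.0136 (exact permutation adjusted p = 0.0278, 7 of 7 animals) and peaks at T-cell and NK-cell markers from 0.0497% ± 0.00773 to 0.0627% ± 0.00622 (exact permutation adjusted p = 0.0278, 5 of 7). These shares rest on few peaks per library. The stromal share hardly changed in animal 7 (0.0149% to 0.0157%) and animal 8 (0.0229% to 0.0238%), so 7 of 7 overstates the rise. The T-cell and NK-cell call was lost with treatments swapped within animals (adjusted p = 0.0804), and its difference was -0.000620 with peaks within 25 kb of a TSS. No single gene passed among 3 stromal, 5 T-cell and NK-cell, 3 neutrophil, 8 dendritic-cell and 1 erythroid marker tested by limma, with 1, 2, 0, 2 and 1 changed when adjusted over the list alone. Fn1, with 0.286 ± 0.488 and 1.00 ± 0.535 peaks (adjusted p = 0.103), and Bcl11b, with 0.143 ± 0.378 and 1.25 ± 0.707 (adjusted p = 0.0972), had the largest differences of the stromal and T-cell lists. The shares of dendritic-cell, neutrophil and erythroid markers had exact permutation adjusted p of 0.951, 0.951 and 0.0868, and B-cell markers, with 0 genes over the peak minimum, had 0.000705% ± 0.00186 and 0.000991% ± 0.00280 (exact permutation adjusted p = 1). With single animals left out, 0 lists passed without animals 1, 3, 5 or 7 and 2 passed without animal 8. The interferon difference then stayed at 0.114 to 0.134 percentage points and the stromal one at 0.0132 to 0.0180, and 3 of the 4 lost interferon calls had the smallest p that the arrangements allow.

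Distal peaks with the AP-1 motif rose from 20.5% ± 1.38 in media (SD, n = 7) to 28.8% ± 1.59 with LPSx1 (SD, n = 8; exact permutation adjusted p = 0.00849), higher in 7 of 7 animals. The difference was 9.05 percentage points in lanes 1 and 2 and 7.21 in lanes 3 and 4. Distal peaks with the motif of PU.1, the pioneer factor of macrophages, fell from 14.8% ± 0.716 to 12.7% ± 0.849 (exact permutation adjusted p = 0.00849, lower in 7 of 7), a difference absent over all peaks (0.00155 percentage points). The GC-rich SP/KLF motif fell from 2.27% ± 0.975 to 1.30% ± 0.352 (exact permutation adjusted p = 0.0170, 7 of 7). The NF-kB motif rose from 3.73% ± 0.793 to 4.66% ± 0.632 (exact permutation adjusted p = 0.0255, higher in 6 of 7), a call lost with treatments swapped within animals (adjusted p = 0.0645). The other 7 motifs did not pass, with C/EBP at 14.8% ± 1.29 and 16.5% ± 1.70 (exact permutation adjusted p = 0.0870). With single animals left out, the NF-kB call was lost in 6 of 8 cases and the SP/KLF call in 2. The AP-1 and PU.1 calls were kept in each. Without animal 8 the number of motifs that passed was 2.

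**Figure D1:**
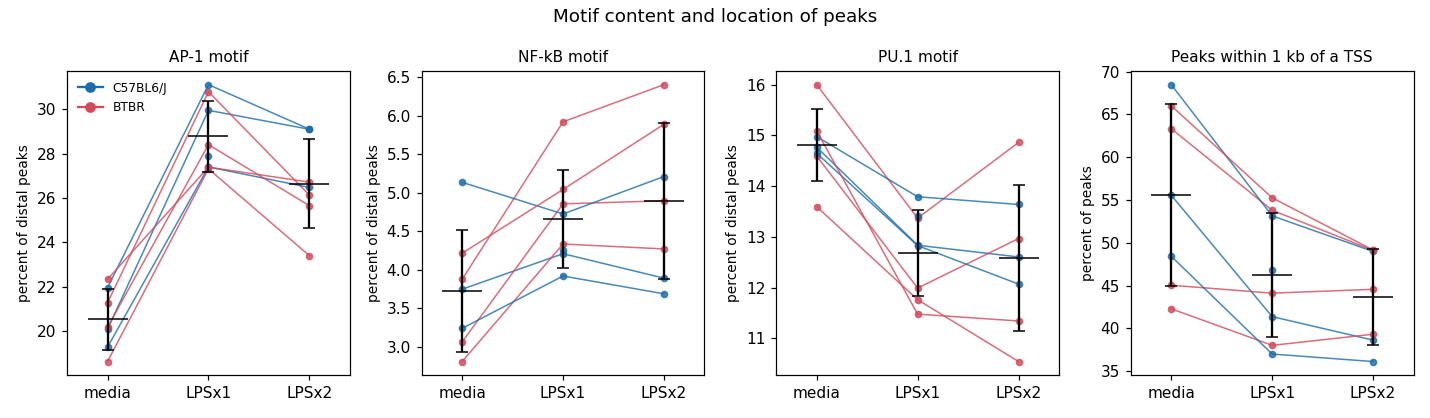
Percent of distal peaks with the AP-1, NF-kB or PU.1 motif and percent of all peaks within 1 kb of a TSS, per library (points, joined within an animal; blue C57BL6/J, red BTBR) in media, LPSx1 and LPSx2, with the mean and SD over the libraries of a treatment in black. The AP-1 share was higher with LPSx1 and with LPSx2 than in media in 7 of 7 animals.

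With LPSx1 a smaller share of peaks lay at promoters. Those within 1 kb of a TSS made up 55.6% ± 10.6 in media (SD, n = 7) and 46.2% ± 7.24 with LPSx1 (SD, n = 8), lower in 7 of 7 animals (exact permutation p = 0.00463). The difference was -7.70 percentage points in lanes 1 and 2 and -13.7 in lanes 3 and 4, and with lists as deposited it did not pass (-10.8 points, exact permutation p = 0.0602). At the level of regions, 842 were gained and 528 lost among 44996 (exact permutation p = 0.0156, the smallest that 64 arrangements can give, with at most 477 in the others). The balance of the 2 directions varied with the choice of lists, a change whose cause was not tested: 1729 were gained and 124 lost with lists as deposited, 1255 and 20 with no library left out as well, and 1158 and 1139 without the 7 lists with duplicates. Lists as deposited were not of equal length, and the merged LPSx1 list was longer than the media list in 6 of 7 animals. With no library left out, the media list of animal 6 held 299 peaks. Of the gained regions 7.24% lay within 1 kb of a TSS, against 43.0% of the lost. The AP-1 motif occurred in 53.1% of 781 gained distal regions and 22.7% of 28613 other distal regions (Fisher's exact test, p = 2.04e-73, where neighbouring regions are not independent). The other regions were called neither gained nor lost and can include some that changed in fewer animals. PU.1 occurred in 20.3% of 301 lost distal regions and 12.3% of the other distal regions. Tnfrsf1b had 4 gained regions, Tet2 and Tiparp 3 each, and Cd300a and Coro1c lost 3 each. Regions detected in 8 of 8 LPSx1 and 0 of 7 media libraries included intergenic ones at chromosome 1, 6445380 to 6445704, nearest to St18, and chromosome 1, 57370509 to 57370788, nearest to 1700066M21Rik. An intron of Ncoa2 (chromosome 1, 13206914 to 13207192) was detected in 7 of 7 media and 0 of 8 LPSx1 libraries.

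With repeated exposure to LPS, Pde4b rose by 5.21 ± 0.665 peaks over media (limma adjusted p = 0.00121) to 10.4 ± 2.57 (SD, n = 7), higher in 7 of 7 animals. Tiparp, a target of the aryl hydrocarbon receptor, rose from 2.43 ± 1.27 in media (SD, n = 7) to 5.71 ± 2.14 peaks (adjusted p = 0.00121, 7 of 7), and Schip1 from 1.14 ± 1.22 to 4.86 ± 1.77 (adjusted p = 0.00456, 7 of 7). Ncoa7 rose by 4.54 ± 0.761 peaks (adjusted p = 0.00571, 7 of 7). Slc31a2 rose to 7.86 ± 3.81 (adjusted p = 0.00591, 7 of 7). Tet2 rose to 9.29 ± 3.15 (adjusted p = 0.00863, higher in 5 of 7 and lower in 0), a call lost without animal 7 (adjusted p = 0.0615). Hes1 fell to 1.43 ± 0.787 (adjusted p = 0.00246), Cd300a to 1.43 ± 1.40 (adjusted p = 0.00121), Mthfs to 1.86 ± 1.22 (adjusted p = 0.00652) and Lyzl4 from 3.86 ± 1.68 to 1.29 ± 1.98 (adjusted p = 0.00258), each lower in 7 of 7 animals. Cebpb, a C/EBP factor of inflammatory macrophages, had the largest difference (6.25 ± 1.69 peaks, adjusted p = 0.0431, higher in 5 of 7 and lower in 2), but its call was lost without any of animals 1 to 6.

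**Figure D2:**
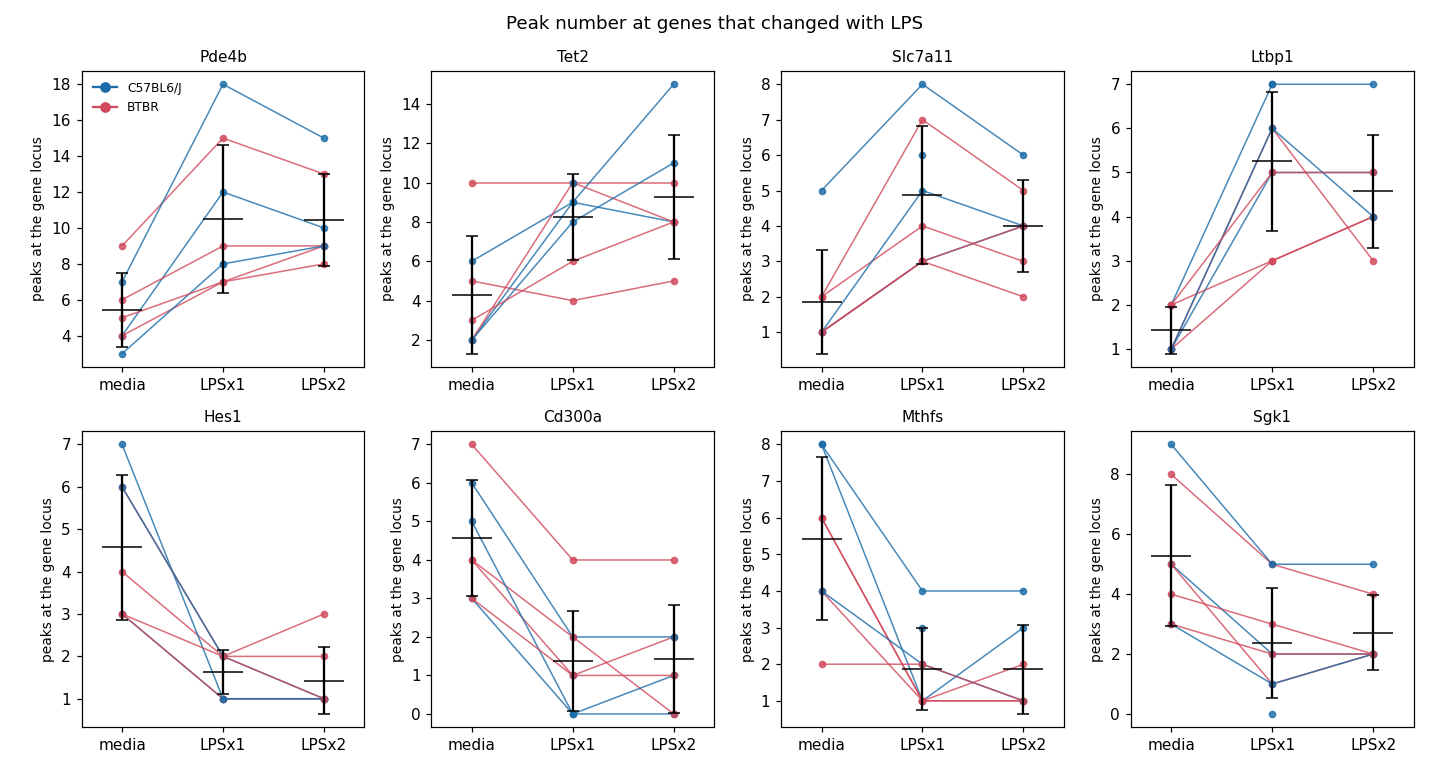
Number of peaks assigned to 8 genes per library (points, joined within an animal; blue C57BL6/J, red BTBR) in media, LPSx1 and LPSx2, with the mean and SD over the libraries of a treatment in black. Pde4b was higher and Cd300a lower in 7 of 7 animals with LPSx1 and with LPSx2 than in media.

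With LPSx2, 311 genes rose and 275 fell among 9123, with 2225 at an unadjusted p under 0.05. The other named rises were Pfkfb3, an activator of glycolysis, Ppm1h, Cmip, N4bp1 and Tnfrsf1b, with differences of 3.58 to 4.42 peaks. The other named falls were Elmo1, Tex44, Cdkn2aipnl, Sgk1 and the interferon-gamma receptor gene Ifngr2, with differences of -3.08 to -2.58. Of the 22 named genes, 11 passed with each animal left out: Pde4b, Slc31a2, Ncoa7, Schip1, Tiparp, Mthfs, Hes1, Cd300a, Tex44, Lyzl4 and Sgk1. The other 11 lost their call without at least 1 animal, with adjusted p up to 0.211, among them N4bp1 without animal 4 (0.0681) and Ppm1h without animal 4 or 7. The count fell to 311, 338, 197, 244, 243 and 266 without animals 1, 3, 4, 5, 7 and 8, and no other of 64 arrangements gave more than 374. It was 106 in lanes 1 and 2 alone (52 among the 586). No count is given for lanes 3 and 4 alone, where C57BL6/J media and LPSx2 had 1 library each. The count was 0 with lists limited within an animal (585 with the animal as a block). It was also 0 with lists as deposited, where Elmo1, Lyzl4 and Sgk1 lay on the other side of 0. Hes1 did so in the stronger 50% of each list.

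By list, peaks at interferon-stimulated genes rose to 0.253% ± 0.0365 with LPSx2 (SD, n = 7), at inflammatory cytokines and mediators to 0.292% ± 0.105, at antimicrobial, acute-phase and scavenger genes to 0.292% ± 0.109 and at stromal and fibroblast markers to 0.0409% ± 0.00566 of gene-assigned peaks. Each was higher than in media in 7 of 7 animals (exact permutation adjusted p = 0.0208). With treatments swapped within animals (adjusted p = 0.0703) or without animals 1, 2, 3, 4, 7 or 8 (0.0625) none of the 4 passed, but each p was then the smallest the arrangements allow (0.0156 and 0.0139). With single animals left out the cytokine difference stayed at 0.0972 to 0.147 percentage points, the interferon one at 0.0845 to 0.105, the antimicrobial one at 0.0746 to 0.117 and the stromal one at 0.0170 to 0.0208. Between lanes 1 and 2 and lanes 3 and 4 the cytokine difference went from 0.168 to 0.0732 and the antimicrobial one from 0.153 to 0.0355, and the interferon one was 0.0961 and 0.101. With lists as deposited or the stronger 50% of each list 0 lists passed. The cytokine genes that rose were Cxcl1, a neutrophil chemokine, Il12a, Ptges and Ptgs2, the inducible cyclooxygenase, 4 of 22 tested (5 adjusted over the list alone). Cxcl1 rose from 0.714 ± 1.11 to 2.71 ± 1.25 peaks (limma adjusted p = 0.0132, 7 of 7 animals), and Ptges from 0 in every media library to 1.86 ± 0.378 (adjusted p = 0.00484, 7 of 7). Gbp5 and Parp14 rose among 26 interferon-stimulated genes (6 adjusted over the list alone), and Camp, Fpr1, Fpr2, Hp and Slc7a11 among 20 antimicrobial genes (8 up and 1 down when adjusted over the list alone).

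In the other lists, Tlr4 rose from 3.43 ± 1.81 to 6.57 ± 2.44 peaks (limma adjusted p = 0.0419, higher in 6 of 7 animals), the only call among 19 LPS sensing genes and 1 when adjusted over the list alone. Bcl3 rose and Rela, Sqstm1 and Zfp36, a destabiliser of cytokine mRNA, fell among 23 NF-kB pathway genes (5 up and 5 down when adjusted over the list alone). Il4ra rose among 13 alternative activation genes (1 up and 3 down when adjusted over the list alone). Cebpb rose, and the lysosomal protease gene Ctsb and Lgals3 fell, among 23 macrophage identity genes (4 up and 4 down when adjusted over the list alone). Jund, Fasn, Ccnb2 and Flt3 fell in the lists of the AP-1 family, cholesterol efflux, cell cycle and dendritic cells (4, 1, 1 and 3 changed when adjusted over the list alone). Bcl11b rose among T-cell and NK-cell markers (2 when adjusted over the list alone). By limma 0 antigen presentation, stromal, erythroid and neutrophil genes passed (1, 1, 1 and 0 when adjusted over the list alone). With treatments permuted exactly within lanes, the shares of the 14 other lists had adjusted p of 0.0667 or more.

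The AP-1 motif rose to 26.7% ± 2.00 of distal peaks with LPSx2 (SD, n = 7; exact permutation adjusted p = 0.0170, higher in 7 of 7 animals), by 6.46 percentage points in lanes 1 and 2 and 5.67 in lanes 3 and 4. The NF-kB motif rose to 4.89% ± 1.02 (exact permutation adjusted p = 0.0170, 7 of 7). The E-box of the MiT family fell from 0.313% ± 0.0775 to 0.231% ± 0.0488 (exact permutation adjusted p = 0.0170, 7 of 7), and PU.1 to 12.6% ± 1.44 (exact permutation adjusted p = 0.0255, 7 of 7), though over all peaks its difference was 0.167 percentage points. SP/KLF fell to 1.22% ± 0.254 (exact permutation adjusted p = 0.0407, 6 of 7), a call lost with treatments swapped within animals (adjusted p = 0.103). Without animals 3, 4, 7 or 8, 0 motifs passed, and without animal 5 it was 3. In those 4 cases AP-1, NF-kB and the E-box had the smallest p that 144 arrangements allow (0.0139, adjusted p = 0.0509). With single animals left out the AP-1 difference stayed at 5.64 to 6.41 points. Peaks within 1 kb of a TSS made up 43.7% ± 5.63 with LPSx2 (exact permutation p = 0.00463, the smallest that 432 arrangements can give, lower in 7 of 7). The difference was -8.17 percentage points in lanes 1 and 2 and -16.8 in lanes 3 and 4.

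With LPSx2, 946 regions were gained and 636 lost (exact permutation p = 0.0156, the smallest possible, with at most 850 in the other arrangements). With lists as deposited 1800 were gained and 203 lost, with no library left out as well 633 and 25, and without the 7 lists with duplicates the balance turned, to 1277 and 1574. The AP-1 motif occurred in 47.4% of 879 gained distal regions and 22.7% of 28535 called neither gained nor lost (Fisher's exact test, p = 5.61e-56), NF-kB in 10.6% and 4.92% (p = 2.54e-11) and C/EBP in 27.3% and 18.8% (p = 1.49e-09). Pde4b and Tnfrsf1b had 4 gained regions each, and Maf, Slc31a2, Tet2, Tiparp and Upp1 had 3 each. An intron of Il1rl1, the gene of the IL-33 receptor (chromosome 1, 40444780 to 40445023), was detected in 7 of 7 LPSx2 and 1 of 7 media libraries. The intron of Ncoa2 lost with LPSx1 was detected in 0 of 7 LPSx2 libraries.

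The 2 responses overlapped: 189 genes rose and 138 fell with both LPSx1 and LPSx2, and 0 moved in opposite directions. Independent lists of these sizes would share 10.3, 6.30 and 16.2 genes, and groups simulated without change against the same media libraries shared 0, which adds little, since those groups held no effect to call. With the media libraries split so that each comparison had its own, fewer genes passed (129 with LPSx1 and 148 with LPSx2 in one split, 88 and 133 in the other). Of these, 30 and 27 genes rose in both, 8 and 7 fell in both, and 1 and 0 moved oppositely. Across genes, which are not independent replicates, the differences correlated at 0.868, against 0.514 in simulated unchanged groups (at most 0.789) and 0.483 and 0.528 with split media. The covariance was 0.395, against 0.0793 simulated and 0.271 and 0.285 with split media.

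No gene passed between LPSx2 and LPSx1 in limma (415 at an unadjusted p under 0.05, with 456 expected by chance). The genes with the smallest p were Hsd11b1, which reactivates glucocorticoids, at 2.00 ± 0 peaks with LPSx2 (SD, n = 7) and 1.25 ± 0.463 with LPSx1 (SD, n = 8), and Pole4, Nxt1, Macrod1 and Arl4a on the higher side. On the lower side they were Tmem183a, Txlnb, Lztfl1, BC005537 and Uprt (limma adjusted p = 0.797 for all 10). Among list members Rsad2 stood at 1.29 ± 1.11 with LPSx2 and 2.63 ± 1.19 with LPSx1 and Il12a at 1.71 ± 1.38 and 0.750 ± 0.707 (adjusted p = 0.98 for both). For the 18 lists, 0 shares passed, with exact permutation adjusted p of 0.858 or more, and 0 members passed when adjusted over any list alone. Within C57BL6/J 324 genes and within BTBR 409 had an unadjusted p under 0.05, with 0 passing in limma.

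The AP-1 motif share was lower with LPSx2 than with LPSx1 in 7 of 7 animals, by -2.13 percentage points (26.7% ± 2.00, SD, n = 7, and 28.8% ± 1.59, SD, n = 8; exact permutation p = 0.0231, adjusted p = 0.127). The E-box (-0.0352 points, exact permutation adjusted p = 0.127) and the ISRE (-0.336, exact permutation adjusted p = 0.130) were also lower in 7 of 7. With treatments swapped within animals, the AP-1 motif and the E-box passed (exact permutation adjusted p = 0.0430 for both) and the ISRE did not (0.0573). Without animal 7, 2 motifs passed without swapping within animals, with an adjusted p of 0.0255 for AP-1. Of 44996 regions 13 were gained and 9 lost, a count that other arrangements reached (exact permutation p = 0.0625, at most 25 in the others). They included an intron of Dhrs3 (chromosome 4, 144906486 to 144906847) in 7 of 7 LPSx2 and 3 of 8 LPSx1 libraries and the promoter of Rps3 (chromosome 7, 99483525 to 99483929) in 1 of 7 and 7 of 8. Peaks within 1 kb of a TSS made up 43.7% ± 5.63 and 46.2% ± 7.24 (exact permutation p = 0.110).

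Between the strains, Nlrp1b, an inflammasome sensor that varies among inbred mouse strains (chromosome 11, 71153102 to 71230733), had 2.33 ± 0.471 peaks in C57BL6/J animals and was listed at 0 in all BTBR libraries (SD over animal means, n = 4 each; limma adjusted p = 2.84e-07). Gm13283 and Ifi204, a member of the interferon-inducible p200 family, were also listed at 0 in BTBR, against 2.42 ± 0.957 and 1.92 ± 0.569 peaks (adjusted p = 0.000406 and 4.88e-05). The phosphatase gene Inpp4b was lower by -5.31 ± 0.786 peaks (adjusted p = 0.00418), with 1.92 ± 1.10 in BTBR and 7.50 ± 2.58 in C57BL6/J. Pla2g4a, which releases arachidonic acid for prostaglandin synthesis, stood at 2.67 ± 2.02 and 7.08 ± 2.36 (adjusted p = 4.88e-05), and Iqgap2 at 2.58 ± 0.739 and 6.58 ± 2.13 (adjusted p = 0.000406). On the higher side, Gpr139 had 1.75 ± 0.167 peaks in BTBR and was listed at 0 in C57BL6/J (adjusted p = 4.50e-05). H60b, a ligand of the NK-cell receptor NKG2D, was higher by 2.38 ± 0.286 (adjusted p = 0.000636). Elovl5 of fatty acid elongation had 4.08 ± 0.739 against 2.50 ± 0.577 (adjusted p = 0.00454). The p-values here come from a fit that treats the libraries of an animal as nearly independent. With 1 value per animal 0 of 9123 genes passed, so each of these calls was lost. The animal means of the strains did not overlap at Nlrp1b, Gm13283, Ifi204, Inpp4b, Iqgap2, Gpr139 and Elovl5. These genes were named for their strain differences in the same data, so this adds no separate support.

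**Figure D3:**
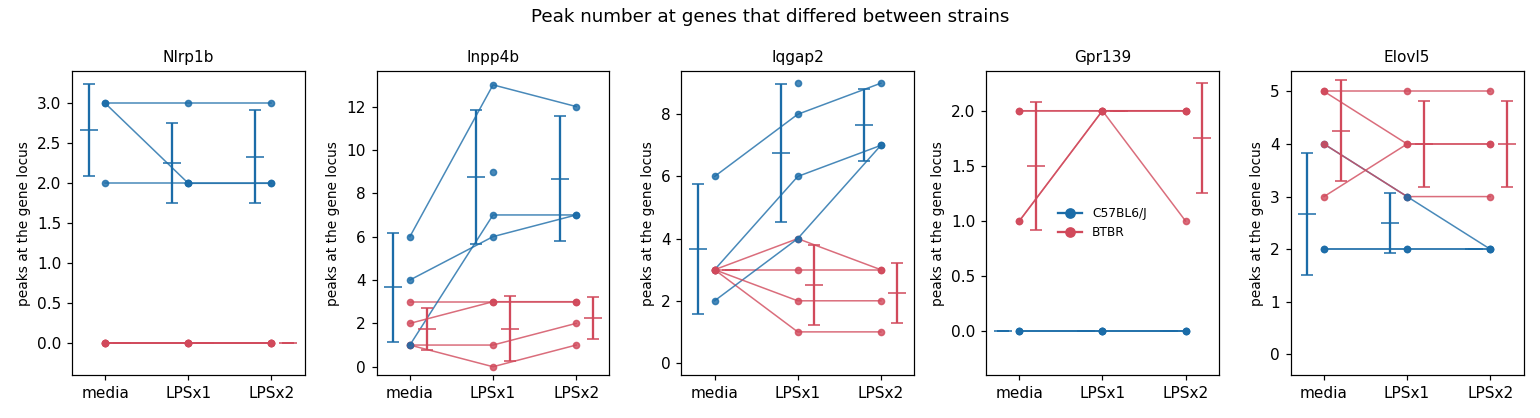
Number of peaks assigned to 5 genes per library (points, joined within an animal) in media, LPSx1 and LPSx2 for C57BL6/J (blue) and BTBR (red), with the mean and SD of each strain beside the points. Nlrp1b was listed at 0 in every BTBR library and Gpr139 at 0 in every C57BL6/J library.

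In the strain contrast 47 genes were higher and 62 lower in BTBR among 9123, with 1158 at an unadjusted p under 0.05. This count rests on treating the libraries of an animal as nearly independent, and it was 0 with 1 value per animal, with lists as deposited and with lists limited within an animal. Of the 35 ways to split the 8 animals 4 gave at least as many genes, with up to 1237 in the others. The 3 others follow pairs of lanes, where a lane cannot be estimated. Without them 1 of 32 did, with at most 47 in the others, and of the 8 splits with 1 animal of each group per lane 1 did, with at most 1. The other genes named by the rule were Fam20c, Lrp1, Plxnd1, Gm11168, Ndfip2, the hexokinase gene Hk3, Filip1, Gm10718 and Bag3 on the higher side and Mtus1, Trim52, Eed, Soga1 and Rpl14 on the lower. Gm11168 and Gm10718 lie in a repeat-rich part of chromosome 9 and Nlrp1b, Ifi204, H60b and Gm13283 have close paralogs, so their peaks are uncertain. Of the 22 named genes 10 passed with each animal left out: Nlrp1b, Gm13283, Inpp4b, Pla2g4a, Mtus1, Iqgap2, Soga1, Rpl14, Gpr139 and H60b. Elovl5 did not without animal 3 (adjusted p = 0.0651), where the count fell to 40. The count was 108 in lanes 1 and 2 alone (28 among the 109). The count in lanes 3 and 4 alone is not interpreted, since C57BL6/J media and LPSx2 had 1 library each there. With lists as deposited Iqgap2 and Eed lay on the other side of 0, and with no library left out Pla2g4a did too. By treatment, 2 genes were higher and 3 lower in media, 7 and 26 with LPSx1 and 4 and 15 with LPSx2.

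By list, Ifi44 was higher and Ifi204 lower among 26 interferon-stimulated genes (5 and 2 when adjusted over the list alone). Ifi44 was listed at 0 in C57BL6/J. The scavenger receptor gene Marco was listed at 0 in BTBR and had 1.17 ± 0.793 peaks in C57BL6/J (SD, n = 4; limma adjusted p = 0.0240), the only call among 20 antimicrobial genes and 1 when adjusted over the list alone. Arg1, the arginase of alternatively activated macrophages, stood at 1.58 ± 0.739 in BTBR and 3.67 ± 1.33 in C57BL6/J (adjusted p = 0.0405), the only call among 13 alternative activation genes and 1 when adjusted over the list alone. Cebpa was lower among 23 macrophage identity genes (3 when adjusted over the list alone), and Ptgs2 stood at 2.42 ± 0.739 and 4.67 ± 1.74 (adjusted p = 0.0504). With 1 value per animal no gene passed between strains, so the calls in this paragraph were lost. Of the other lists, 1 cytokine, 2 LPS sensing and 1 antigen presentation gene differed when adjusted over the list alone, and 0 in the remaining ones by limma. The shares of 18 lists and 11 motifs gave 0 calls (exact permutation adjusted p of 0.698 or more for lists and 0.314 or more for motifs). The C/EBP motif, at 15.1% ± 0.763 in BTBR and 17.2% ± 0.912 in C57BL6/J (n = 4 each), had an exact permutation p of 0.0286, the smallest that 70 arrangements can give. In media alone the order was the other way, at 15.1% ± 1.21 in BTBR (SD, n = 4) and 14.5% ± 1.55 in C57BL6/J (SD, n = 3). The value of C57BL6/J animal 6 rests on its LPSx1 library alone.

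Of 44996 regions, 72 were detected in BTBR alone and 145 in C57BL6/J alone, a count that 1 other of 35 splits of the animals reached (exact permutation p = 0.0571). That split, with 795 regions, sets lanes 1 and 2 against lanes 3 and 4. Alone here means by most libraries of each animal, so a single library of the other strain can hold the region. The C57BL6/J regions nearest to Ogfrl1 and Fam168b were each detected in 1 of 12 BTBR libraries. C57BL6/J animal 6 counts by its LPSx1 library only. Of the 8 splits with 1 animal of each group per lane the real one gave 217 and the others at most 9, though 8 splits cannot give a p under 0.05. Which strain held more regions turned with the choice of lists: 166 lay in BTBR alone and 96 in C57BL6/J alone with lists as deposited, 158 and 51 with lists limited within an animal, and 181 and 6 with no library left out and lists as deposited. In those settings the lists of a lane were not of equal length. Regions in C57BL6/J alone included 3 nearest to Inpp4b (chromosome 8, 81751248 to 81769407) and 3 nearest to Aim2, Ifi207 and Ifi204 (chromosome 1, 173418914 to 173767161). They also included 3 nearest to Pla2g4a and Ptgs2 (chromosome 1, 149840916 to 150167499) and 2 nearest to Nlrp1b (chromosome 11, 71230747 to 71251691). Regions in 12 of 12 BTBR and 0 of 10 C57BL6/J libraries included introns of 1700025G04Rik (chromosome 1, 151953605 to 151953904) and Myo3a (chromosome 2, 22587734 to 22587940). The reads of both strains were aligned to mm10, which is the C57BL6/J sequence, so a missing BTBR peak can also come from sequence that differs or is absent in BTBR.

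In the lists limited within a lane, the response to LPS differed between strains at Gpr176, an orphan receptor gene, and at Tcf25. Gpr176 had 0 peaks in all 4 BTBR media libraries and 1 in each of the other 18 kept libraries. The response in BTBR exceeded that in C57BL6/J by 1.00 ± 0.027 peaks with LPSx1 (limma adjusted p = 2.75e-11) and by 1.00 ± 0.028 with LPSx2 (adjusted p = 4.00e-11). The spread within groups was 0 at this gene, so these p-values rest on the spread borrowed from other genes. Both calls were lost with lists as deposited, lists limited within an animal or to the shortest of all lanes (0.125 and 0.0833 peaks), unmerged peaks, distal peaks alone and no filter on low peak numbers (adjusted p = 0.377 and 0.345). Tcf25 went from 2.00 in C57BL6/J media to 0 with LPSx1 and stayed at 1.00 in BTBR, a difference in response of 2.02 ± 0.295 (adjusted p = 0.0429, with LPSx1 n = 4 and media n = 3 and 4). Its call was lost without any of animals 1 to 7, with adjusted p up to 0.352, and with lists as deposited, lists limited within an animal, unmerged peaks or no filter on low peak numbers. Apart from leaving out an animal, Tcf25 passed in 3 of 14 alternatives. No other gene passed, with 517 and 588 at an unadjusted p under 0.05 for LPSx1 and LPSx2 in limma. Within C57BL6/J 140 genes rose and 96 fell with LPSx1 and 171 and 121 with LPSx2, and within BTBR 19 and 9, and 15 and 4. These counts are not shown to differ, since the interactions gave 2 genes and 1, which 10 and 19 of 35 splits of the animals reached.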

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

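The difference in response at Tcf25 and Gpr176 came from tests planned before the values were seen, and the comparison of the left-out lists with the other libraries was among the tests chosen after. A library stood apart from the 3 others of its group in 40 of 350 groups of 4 tested (by the gap to the next value over the range). About 5% would do so by chance, and equal whole numbers of peaks raise that share. The animals of a group also lay in different lanes, whose lists held 11349, 22037, 16045 and 13957 peaks in lanes 1 to 4. Of the 36 cases of peak numbers at a gene, 2 stood apart after division by that length, Lyzl4 in animal 3 and Rpl14 in animal 8, both with LPSx2. This division, chosen after the values were seen, also removes ties between whole numbers, and 6 other cases stood apart only with it. Apart from those 2, the peak numbers below do not show that a library was unusual. The shares at B-cell markers below rest on very few peaks and do not show it either.

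BTBR animal 3, in the lane with the longest lists, had the highest value in most of the media cases, with 8 peaks at Cd47 (median of the others 3), 15 at Cmip (2), 8 at Elmo1 (2), 8 at Fam20c (3), 14 at Lrp1 (6), 5 at Tiparp (2) and 10 at Tnfrsf1b (5). Its share of peaks at B-cell markers in media was 0.00493% (0 in the others). With LPSx1 it had 14 peaks at Tnfrsf1b (8), and with LPSx2 it had 9 at Eed (3), 3 at Lyzl4 (0), 2 at Mthfs (1), 11 at N4bp1 (4) and 4 at Sgk1 (2).

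BTBR animal 2, in the lane with the shortest lists, had the lowest value at Arid1a in media (2, others 5), at Gm10718 (1, others 3), Gm11168 (2, others 4), Hes1 (1, others 2) and Rpl14 (0, others 1) with LPSx1, and at Gm11168 (2, others 4), Gpr139 (1, others 2) and Ncoa7 (3, others 7) with LPSx2. It had the highest at Gm10718 in media and with LPSx2 (4, others 3 in both), and its share of peaks at dendritic-cell markers with LPSx2 was 0.0189% (others 0.0889%). BTBR animal 8 had the highest share at housekeeping genes (0.198%, others 0.171%) and B-cell markers (0.00792%, others 0) and 2 peaks at Mthfs (others 1) with LPSx1. It had 1 peak at Filip1 in media (others 2), and with LPSx2 4 at Filip1 (others 2), 1 at Rpl14 (others 0) and 0 at Tcf25 (others 1). BTBR animal 5 had 3 peaks at Cdkn2aipnl with LPSx1 (others 4).

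Among C57BL6/J LPSx1 libraries, animal 6 had 0 peaks at Arid1a (others 2) and 3 at Ndfip2 (others 2), animal 4 had 3 at Bag3 (others 1) and 3 at Nlrp1b (others 2), animal 1 had 0 at Filip1 (others 1) and 1 at Gm13283 (others 3), and animal 7 had 4 at Trim52 (others 5).

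The response to LPSx1 differed between strains by 2.02 peaks at Tcf25 and by 1 at Gpr176, and the response to LPSx2 by 1 at Gpr176. Of the 2 lists of C57BL6/J animal 6 that were left out for their length, 93.6% of the 299 peaks in media and 98.6% of the peaks with LPSx2 lay inside regions of the other libraries, which cover 0.466% of the genome. These lists hold few peaks, but at places where other libraries have them.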

How the results depend on the processing

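The alternatives of lanes, uncollapsed peaks, doubled lists, libraries under 5000 peaks, distal peaks only, 1 value per animal and the fit limited within an animal with the animal as a block were tests chosen after the first results were seen. Counts below are of genes, regions, gene list shares and motif shares that passed, with the main counts of 510 genes for LPSx1 against media, 586 for LPSx2 against media, 0 for LPSx2 against LPSx1, 109 between strains, and 2 and 1 for strain differences in response to LPSx1 and LPSx2. Over the alternatives other than leaving out an animal, single values of named genes stayed the same in 518 cases, became weaker in 548 and were reversed in 24. Motif shares stayed the same in 48 and became weaker in 40, list shares in 25 and 64. For each change below the cause was not tested unless stated.

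With lists as deposited, 0 genes passed for LPSx1, LPSx2, the strains and both strain differences in response, 0 and 0 list shares passed for LPSx1 and LPSx2, and 2 motifs passed for LPSx2. Zfp36l2 (4.51 peaks), Mthfs (0.229), Elmo1 (1.19), Maml3 (0.927) and Sgk1 (2.14) were higher with LPSx1, Elmo1 (1.83), Lyzl4 (0.0417) and Sgk1 (1.38) with LPSx2, and Iqgap2 (1.27) and Eed (2.00) in BTBR. With no library left out and lists as deposited these counts of genes were again 0. Zfp36l2 (3.63), Mthfs (0.375), Elmo1 (0.75), Maml3 (0.875) and Sgk1 (2) were higher with LPSx1, Elmo1 (1.75) and Sgk1 (1.25) with LPSx2, and Pla2g4a (0.5), Iqgap2 (2.42) and Eed (2.92) in BTBR, and regions numbered 658 for LPSx2 and 8 for LPSx2 against LPSx1.

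With lists limited to the shortest of all lanes, 510, 636 and 150 genes passed for LPSx1, LPSx2 and the strains, of which 246, 276 and 50 were shared with the main calls. LPSx2 against LPSx1 gave 1 gene and 39 regions, the strain differences in response 4 and 5 genes, and 2 and 7 list shares passed. Limited within an animal, 0 genes passed in all of these, Eed was higher in BTBR (0.271), 11 regions differed between LPSx2 and LPSx1 and 1 list share passed for LPSx1. With the animal added as a block to that fit, 382 and 585 genes passed for LPSx1 and LPSx2 and 0 for both strain differences in response.

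With the stronger 50% of each list, 206, 299, 1 and 45 genes passed for LPSx1, LPSx2, LPSx2 against LPSx1 and the strains (198 of the 299 up), 1 and 0 strain differences in response, and 589, 729 and 112 regions for LPSx1, LPSx2 and the strains. List shares gave 0 and 0 and motifs 2 and 0, and Hes1 was higher with LPSx1 (0.104) and LPSx2 (0.0833).

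With the replicate number as a block, 354 and 534 genes passed for LPSx1 and LPSx2, 3 for the strain difference in response to LPSx2, 0 list shares for LPSx2 and 2 motifs for LPSx2 against LPSx1. Without the lane in the model 112, 149 and 17 genes passed for LPSx1, LPSx2 and the strains (81 up and 31 down, 100 and 49, 3 and 14). With peaks within 25 kb of a TSS 51 genes passed between strains, 186 rose and 262 fell with LPSx2, 2 list shares passed for LPSx1, and the T-cell and NK-cell share differed by -0.000620. On the log2 scale 68 genes were higher and 58 lower in BTBR. With no filter on low peak numbers 829, 924, 1 and 184 genes passed for LPSx1, LPSx2, LPSx2 against LPSx1 and the strains (358 up and 471 down, 370 and 554 for the first 2), and 0 for the strain difference in response to LPSx1. With 1 value per animal 0 genes passed between strains.

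With overlapping peaks not collapsed, 664, 1294 and 201 genes passed for LPSx1, LPSx2 and the strains (325 up and 339 down for LPSx1), 0 and 0 strain differences in response, 55 regions between LPSx2 and LPSx1 and 3 list shares for LPSx1. With distal peaks only, 614 genes rose and 141 fell with LPSx1, 651 and 147 with LPSx2, 201 differed between strains and 0 and 0 in response, and Gm11168 differed by -0.0841. Over all peaks instead of distal peaks 10, 8 and 1 motifs passed for LPSx1, LPSx2 and LPSx2 against LPSx1, and PU.1 differed by 0.00155 and 0.167 points.

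With the 7 lists with doubled peaks left out, 97, 91, 34, 54 and 72 genes passed for LPSx1, LPSx2, LPSx2 against LPSx1 and the 2 strain differences in response (36, 28, 0, 1 and 1 shared with the main calls). Regions numbered 2297, 2851, 357 and 411 for LPSx1, LPSx2, LPSx2 against LPSx1 and the strains, and 0 list shares and 0 motifs passed. In lanes 1 and 2 only, the genes numbered 112, 106, 37, 42 and 50 for LPSx1, LPSx2, LPSx2 against LPSx1 and the 2 strain differences in response. The regions there numbered 3046, 2917, 313 and 923 for LPSx1, LPSx2, LPSx2 against LPSx1 and the strains. In lanes 3 and 4 only 358 genes differed between LPSx2 and LPSx1 (0 shared), 379 and 423 in response and 542 between strains, with 6036, 7701, 2734 and 2430 regions. In lanes 3 and 4, and without the lists with doubled peaks, C57BL6/J media and LPSx2 had 1 library each. The gene counts of those settings are therefore not interpreted. That 0 genes were shared for LPSx2 against LPSx1 carries no information, because the main comparison called 0. In either pair of lanes 0 list shares and 0 motifs passed. By construction regions rise in number with fewer animals, because the rule then asks for fewer of them, and with few libraries the permutations of shares cannot give small p-values.

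Without 1 animal at a time, the genes numbered 191 (animal 7) to 431 (animal 2) for LPSx1, 197 (animal 4) to 561 (animal 2) for LPSx2, 0 to 3 (animal 2) for LPSx2 against LPSx1, 40 (animal 3, 12 up and 28 down) to 121 (animal 7) between strains, and 1 (animal 6) to 5 (animal 1) and 2 to 6 for the strain differences in response. Regions numbered 1370 to 2435, 1583 to 3052, 22 to 154 and 257 to 425 for LPSx1, LPSx2, LPSx2 against LPSx1 and the strains. List shares numbered 0 to 7 for LPSx1 and 0 to 4 for LPSx2, and motifs 2 to 5, 0 to 7 and 0 to 2 for LPSx1, LPSx2 and LPSx2 against LPSx1. With lists as deposited, duplicates included, the log2 peak number of LPSx2 against LPSx1 ranged from -0.400 (without animal 4) to 0.204 (without animal 6). It was 0.268 without the libraries under 5000 peaks.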

Other observations

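The tests of list length, of library depth, of lists with doubled peaks, of clustering along chromosomes, of the strain variant, of strain differences in list and motif shares and of all splits of animals were chosen after the results were seen, and the tests of GC content and repeats before.

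The higher AP-1 motif share of distal peaks with LPSx1 than in media was weighed against GC content, list length, library depth and doubled lists. Within animals, between lists limited to equal length, the share was higher by 8.38 ± 1.60 percentage points (SD, n = 7), and by 7.82 with the peaks weighted to the same GC content, in 7 of 7 animals. In the 4 animals whose lists hold no doubled peaks it was higher by 7.99, from 5.05 to 9.52. After merging, only 1 animal, number 8, had a shorter list with LPSx1 than in media, with a difference of 5.05 against 8.93 in the 6 others. Before merging, the LPSx1 list was also the shorter in animals 3 and 4, whose media lists held duplicates. The group difference was 5.82 points with lists as deposited and 8.25, 9.07 and 7.34 with lists limited within a lane, over all lanes and within an animal, and it passed in each (exact permutation). Unequal list length is thus not the whole of this pattern, while library depth, which can also affect which peaks rank highest, remains open with 1 animal to compare. Across 10 alternatives the group difference ran from 5.82 to 10.0 points and passed in 7, with adjusted p from 0.00566 to 0.153. It did not pass in the 3 with fewer libraries, which were lanes 1 and 2 (9.05), lanes 3 and 4 (7.21) and the lists without duplicates (7.18).

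The lower AP-1 motif share with LPSx2 than with LPSx1 is a hypothesis, since it did not pass after adjustment. Within animals it was -2.26 ± 1.59 points (SD, n = 7), and -2.32 when weighted to the same GC content, lower in 7 of 7. It was lower in 3 of 3 animals whose merged LPSx2 list was the shorter (-2.53) and in 4 of 4 whose merged list was the longer (-2.05). Length of the merged lists alone may thus not account for it. Before merging, only animal 5 had the shorter LPSx2 list (-2.75), so on that basis list length stays open. Across 10 alternatives the group difference ran from -2.59 to -0.601 and passed in 1, the one with treatments swapped within animals, with adjusted p from 0.0430 to 0.716.

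Regions detected in C57BL6/J and not in BTBR were weighed against repeats, a strain variant and clustering. Repeat-masked bases made up 14.9% of them and 13.3% of other distal regions, a difference of 1.66 points (permutation p = 0.302). A strain variant against the reference would give more regions in C57BL6/J alone than in BTBR alone, which held in 2 of 4 settings of list length. In the 2 others, lists as deposited and lists limited within an animal, the lists of a lane were not of equal length. Those 2 settings cannot decide the question, which stays open. Of the 145 regions, 22 pairs of neighbours lay within 1 Mb, against a median of 12 and at most 25 in random draws of regions (permutation p = 0.0043), among them those at Pla2g4a and Ptgs2, at Aim2, Ifi207 and Ifi204, at Nlrp1b, at Inpp4b, at Iqgap2 and at Soga1 and Src. The 72 regions in BTBR alone gave 7 pairs against a median of 3 (permutation p = 0.0335). The draws were not matched for distance to a TSS, and several pairs lay at the same gene. Clustering therefore cannot tell stretches of the genome that differ between the strains from neighbouring peaks of the same gene.

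Splits of the animals put the gene counts in context. For LPSx1 and LPSx2 against media 1 of 64 arrangements, the real one, gave as many genes, with at most 179 and 374 in the others, and for LPSx2 against LPSx1, with 0 genes, 64 of 64 necessarily did, which tests nothing. Between strains 4 of 35 splits gave at least 109 genes, and for the strain differences in response 10 and 19 of 35 gave at least 2 and 1. The 3 larger strain splits follow pairs of lanes, where the model cannot estimate a lane, and gave 1237, 1222 and 1075 genes. Without them 1 of 32 splits gave as many, with at most 47 in the others, and for the differences in response 8 and 16 of 32. Of the 8 splits with 1 animal of each group per lane, 1 gave as many, with at most 1 gene in the others, though 8 splits cannot give a share under 0.05.

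Strain differences in the response of list and motif shares did not pass after adjustment over 30 items (BTBR n = 4, C57BL6/J n = 3, exact permutation over 35 arrangements). The C/EBP motif share of distal peaks differed from media by 3.33 points with LPSx1 and 3.58 with LPSx2 in C57BL6/J, and by -0.0987 and 0.0230 in BTBR (adjusted p = 0.343 and 0.214). With LPSx2 the AP-1 share differed from media by 7.79 points in C57BL6/J and 4.87 in BTBR, the NF-kB share by 0.223 and 1.88, and the share of peaks at inflammatory cytokines and mediators by 0.214 and 0.0626 (each exact permutation p = 0.0286, the smallest possible, adjusted p = 0.214).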
